A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

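Total RNA of wild-type Saccharomyces cerevisiae was measured in 4 libraries, 2 replicates (A and B, which the labels call biological) of each of 2 growth conditions. Per the labels' protocols, cells grew at 30 °C in synthetic complete medium with 2% glucose (NR) or 0.05% glucose (CR), RNA was extracted with the QIAGEN miRNeasy kit, fragmented with an Ambion reagent and made into libraries with an Illumina kit for small RNA. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie (version not given in the sources used here) and Cufflinks 2.0.2 were used, with the yeast build sacCer2. Their settings, the handling of reads with several matches and the use of strand are not given in the sources used here. The authors deposited 1 table of FPKM, fragments per kilobase of feature scaled to the mapped fragments of the library, with 1 column per library and replicates kept apart. All 4 columns were matched to samples by name and 0 were left over.

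The table held 7133 rows, of which 6720 had a gene ID. Gene names, positions and annotation came from the RefSeq annotation of R64. The notes name sacCer2, but of 6025 gene IDs found in R64 the file position of 5989 equalled that of R64 once 1 was added to the start, so positions are given as R64, counted from 1. Of the other 36 rows 23 did not touch the R64 gene of that name, 12 of them rows of cytosolic ribosomal proteins. A further 695 gene IDs were not in RefSeq. Of 413 rows without a gene ID, 411 were matched by position to noncoding genes, mostly 299 transfer RNA and 76 small nucleolar RNA (snoRNA) genes, and 284 were at 0 in every library. These rows were kept out of the test, which used gene rows with a mean of 1 FPKM or more, 6355 in all. Of these, 600 were not in RefSeq, 1151 overlapped another kept row by 1 nt or more, and 60 had under 50% of their 32-nt stretches unique in the genome. At 0 in every library were 194 gene rows.

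Read counts were not used here. For low genes longer than 1500 nt, a product of FPKM and length in kb between 0.02 and 0.04 was read as 1 fragment, which gave 0.0350, 0.0280, 0.0258 and 0.0243 FPKM kb per fragment for NR A, NR B, CR A and CR B from 5, 7, 5 and 5 genes. The window itself held these estimates between 0.02 and 0.04, and no interval was drawn from them.

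CR was compared with NR with limma 3.58.1 in R 4.3.3 (linear fit, moderated two-sided test with an intensity trend) on log2(FPKM + 1), with no covariate and Benjamini-Hochberg adjustment over the 6355 genes at 0.05. The 36 gene lists and the rule for named genes were written before the data were examined. Of the lists, 33 had 3 or more tested members, and the lists of small nucleolar and nuclear RNAs, transfer RNA genes and ribosomal RNA genes had no gene row, so their rows without a gene ID are described in the closing part. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold with 10 FPKM or more in the higher group and both CR libraries on the same side of both NR libraries, up to 4 members of each list with the smallest adjusted p (or, where none passed, the 2 most abundant), and a fixed set of sentinel genes. Of the genes, 12 were in more than 1 list. Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6 prepared the tables and matplotlib 3.10.9 drew the plots.

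The fit was tested on simulated data of CR against NR with 6355 genes, 200 of them changed, in 10 runs. It recovered 0.6% of genes changed by 1 on the log2 scale and 56.1% of those changed by 2, with 0 in the wrong direction, and 5.97% of its calls were false. A list made to rise was called in 10 of 10 runs and an unchanged list in 0. Simulated genes varied independently and with equal spread in both groups. In the data the replicate SD was 0.38 in NR and 0.64 in CR, and the estimated correlation of the ribosome biogenesis list was 0.86. The runs therefore do not show how camera or the gene calls behave under such correlation and spread. They also changed only 200 genes, against 1962 called in the data. The Benjamini-Hochberg cutoff depends on the share of changed genes, so the recovery rates do not carry over to these data.

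Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or a mean of 10 FPKM or more, scaling to a common median, quantile normalization, the replicate letter as a block, no intensity trend, leaving out each library in turn, a 2-fold threshold, an estimated correlation in camera, and fry in place of camera. Added after seeing the data were 4 choices of rows: those at their R64 position, those overlapping no other row, those with 50% or more of their 32-nt stretches unique, and all rows with noncoding ones included. Further lists written after the results were seen are described in the closing part as such.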

Results

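Budding yeast (Saccharomyces cerevisiae) labelled wild type was grown at 30 °C in synthetic complete medium with either 2% glucose, the non-restricted condition (NR), or 0.05% glucose, the calorie-restricted condition (CR). RNA sequencing of total RNA gave 1 expression value per gene and library, as FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library). Each condition had 2 biological replicates, A and B. The time and cell density of harvest are not given in the sources used here. The median FPKM of gene rows was 52.6 in NR A, 48.6 in NR B, 57.6 in CR A and 52.8 in CR B. No read totals were used. From the values of 5, 7, 5 and 5 long, low genes, 1 fragment over 1 kb was estimated to be worth 0.0350 FPKM in NR A, 0.0280 in NR B, 0.0258 in CR A and 0.0243 in CR B. On these estimates a gene of 1 kb at 10 FPKM stood on 286 to 411 fragments. The estimates could only fall between 0.02 and 0.04 FPKM kb, the window used to pick the values, so they do not measure depth. Noncoding RNA genes listed without a gene ID made up 34.0%, 29.9% and 27.4% of all FPKM in NR A, NR B and CR A but 87.2% in CR B. These are shares of summed FPKM, in which short rows weigh more, and not shares of fragments.

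**Figure D1:**
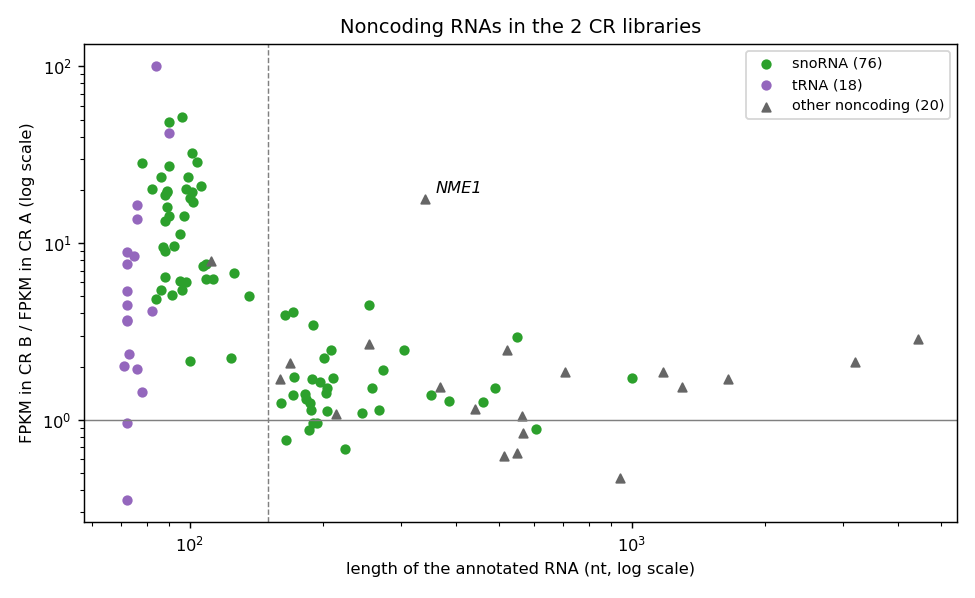
FPKM in CR B over FPKM in CR A against the annotated length in nt of 76 snoRNAs, 18 transfer RNAs and 20 other noncoding RNAs with a mean of 1 FPKM or more over the 4 libraries and above 0 in both CR libraries, with both axes on a log scale and a dashed line at 150 nt. The 40 small nucleolar RNAs (snoRNAs) under 150 nt had a median ratio of 13.8, the 36 longer ones 1.41, and NME1, the RNA of RNase MRP, a ratio of 17.8.

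The comparison asked which transcripts changed when glucose was restricted. In CR, 15 of 16 genes for gluconeogenesis and the use of small carbon compounds rose, as did 15 of 16 of peroxisomal fatty acid oxidation, 14 of 23 of the respiratory chain and 15 of 20 for storage carbohydrates. Of ribosome biogenesis genes 56 of 75 fell, and so did 8 of 17 glycolytic genes and the low-affinity glucose transporter genes HXT1 and HXT3. These 6 lists passed the camera set test at its preset correlation, each with an adjusted p = 0.685 with an estimated correlation. That shared value comes from the adjustment, as their unadjusted camera p then ran from 0.035 (gluconeogenesis) to 0.39 (glycolysis). The correlation was estimated from only 4 libraries. Of 6355 genes tested, 1126 were higher and 836 lower in CR, 30.9% of them in all, and 859 and 695 of these changed 2-fold or more. The test was limma on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05, and every log2 fold below is on that scale, which understates the change of low genes. Both CR libraries lay on the same side of both NR libraries for 4640 genes, or 73.0%, where chance gives 33.3% for a single gene. As all genes share the same 4 libraries, setting these percentages side by side is no test. Replicates differed by an SD over genes of 0.38 (log2) in NR and 0.64 in CR, and 2 against 2 libraries cannot reach 0.05 by permutation alone.

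The counts rested on the library that was left out. Without NR A 75 genes were higher and 47 lower, and without NR B 123 and 111, as the spread then came from the CR pair alone. Without CR A they were 1654 and 1668, and without CR B 1621 and 1113. Of the 159 genes chosen by the naming rule, 136 passed the threshold, and 36 of these also passed in all 4 fits that left out a library: ACS1, ADE17, ADH2, ADH4, ADY2, ARO9, ATH1, CGR1, CIT3, CRC1, CTA1, DMC1, EBP2, FBP1, FET4, HXT1, HXT3, ICL1, JEN1, MET28, MMP1, NDE2, NOP58, PCK1, PHM7, PHO3, POX1, RGI2, RRP14, RRP15, SPG1, YAT2, YLR466C-B, YML089C, ZPS1 and ZRT1. The other named genes lost their call without NR A, without NR B or without either. Without the filter on low values 778 genes were higher and 464 lower, and BAR1, CLB1, COX1, ERG5, ERG25, FAR1, FBA1, HO, HTA1, HXK1, HXT4, MAL33, MFA2, PDC1, PNC1, POL30, PRE2, PRE4, PUP3 and SST2 lost their calls. MEI4 lost its call with a pseudocount of 0.1, after quantile normalization and with the rows without a gene ID included. The balance of higher and lower calls rested on scaling. Higher calls made up 57.4% of the total as deposited, 44.9% (955 higher, 1174 lower) once libraries were scaled to a common median and 49.3% (1044 and 1072) after quantile normalization. Median scaling moved the median log2 fold of all genes by -0.13, from 0.06 to -0.07.

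By log2 fold of FPKM + 1, the largest rises among named genes were those of ADY2, ADH2, RGI2 and JEN1. ADY2, an acetate transporter on chromosome III (132273 to 133124, R64 coordinates, 1 coding exon), rose from 22.1 ± 1.21 to 4326 ± 1248 FPKM (mean ± SD, n = 2 here and below), a log2 fold of 7.52 (SE 0.27, adjusted p = 0.00075). ADH2, the alcohol dehydrogenase that oxidises ethanol (XIII, 873291 to 874337), rose from 19.96 ± 2.67 to 2643 ± 731 FPKM, a log2 fold of 6.96 (SE 0.28, adjusted p = 0.00075). JEN1, a lactate and pyruvate transporter (XI, 22234 to 24084), rose from 24.6 ± 0.287 to 2416 ± 468 FPKM, a log2 fold of 6.54 (SE 0.23, adjusted p = 0.00075). The other genes among the 10 largest rises were RGI2 (log2 fold 6.56), YML089C (6.24), CIT3 (6.09), the aromatic aminotransferase gene ARO9 (5.89), SPG1 (5.79), the peroxisomal catalase gene CTA1 (5.23) and FDH2 (5.07). YML089C is absent from RefSeq and overlaps a gene on the other strand. Only 10.9% of the 32-nt stretches of FDH2 are unique in the genome, and its CR values were 55.7 ± 50.9 FPKM, so its level is uncertain.

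Genes for making glucose and for the glyoxylate cycle rose. Of 16 genes in the list for gluconeogenesis, the glyoxylate cycle and the use of small carbon compounds, 15 rose, 16 when adjusted over the list alone, with a median log2 fold of 3.59. The camera set test gave an adjusted p of 3.8e-12 at its preset correlation and adjusted p = 0.685 with an estimated correlation. FBP1, the gluconeogenic bisphosphatase, rose 16.1-fold, from 35.3 ± 1.504 to 568 ± 48.9 FPKM (adjusted p = 0.0015). PCK1, which encodes phosphoenolpyruvate carboxykinase, rose 17.4-fold, and ICL1, which encodes isocitrate lyase of the glyoxylate cycle, 9.48-fold. ACS1, an acetyl-CoA synthetase gene, rose 22.9-fold. Genes of peroxisomal fatty acid oxidation rose too, 15 of 16 of them, also 15 when adjusted over the list alone, and a median log2 fold of 3.86 (camera adjusted p = 9.0e-10, and adjusted p = 0.685 with an estimated correlation). POX1, the acyl-CoA oxidase gene, rose from 6.26 ± 0.666 to 247 ± 84.6 FPKM and CTA1 from 22.7 ± 1.27 to 905 ± 267 FPKM. YAT2 and CRC1, genes for a carnitine acetyltransferase and the mitochondrial carnitine carrier, rose 30.9-fold and 29.2-fold.

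**Figure D2:**
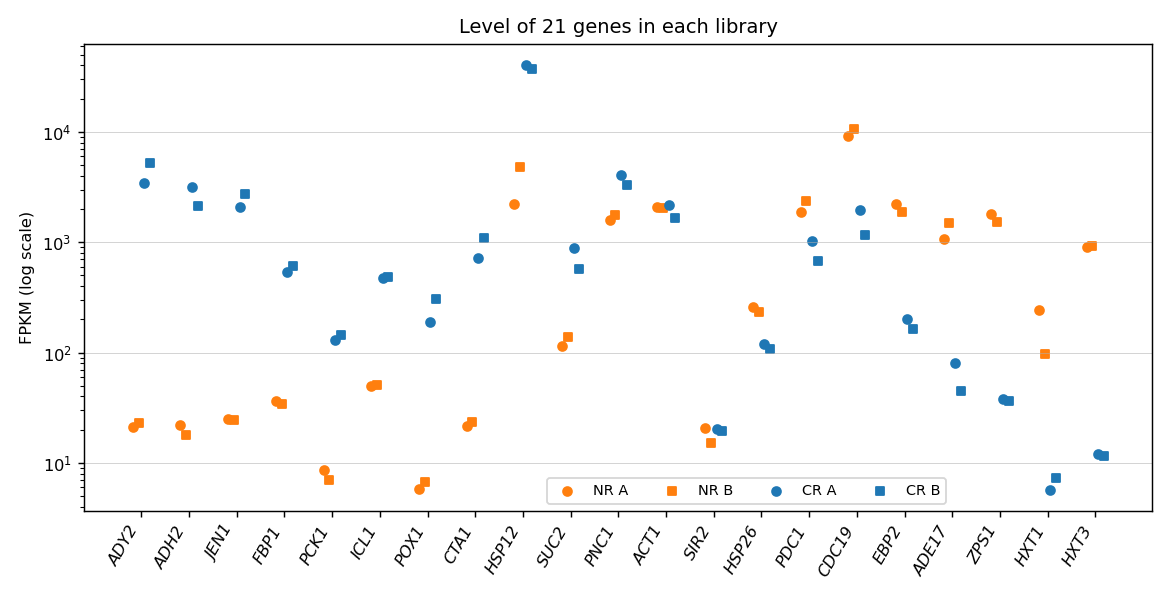
FPKM (log scale) of 21 genes in each of the 4 libraries, with NR in orange, CR in blue, replicate A as circles and replicate B as squares. ADY2 lay at 22.1 FPKM on average in NR and 4326 in CR, and HXT3 at 915 in NR and 11.8 in CR, while ACT1 and SIR2 did not pass the test.

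Of the listed nuclear genes for mitochondrial energy supply and translation that changed, all but 1 rose. In the tricarboxylic acid cycle 9 of 16 genes rose, 11 when adjusted over the list alone (median log2 fold 1.01, camera adjusted p = 0.00038). The mitochondrial citrate and methylcitrate synthase gene CIT3 rose from 9.38 ± 0.309 to 713 ± 151 FPKM, against 487 ± 145 to 1296 ± 13.97 FPKM for CIT1, the main citrate synthase gene. Of 23 respiratory chain genes 14 rose, 15 when adjusted over the list alone (median 1.07, camera adjusted p = 0.00038), among them the NADH dehydrogenase genes NDE2 (10.4-fold) and NDI1 (5.82-fold) and the complex III gene QCR2 (4.19-fold). In ATP synthase 11 of 17 genes rose, 16 when adjusted over the list alone (median 1.15, camera adjusted p = 1.1e-05), with TIM11 up 3.90-fold and the beta subunit gene ATP2 3.59-fold. Mitochondrial ribosomal protein genes had 30 higher and 1 lower of 74, or 38 and 1 adjusted over the list alone (median 0.91, camera adjusted p = 1.6e-06). MRP17 rose 3.43-fold and RSM23 2.74-fold, and the lower gene was MRPS16 (log2 fold -1.14), chosen after its values were seen. Each of these 4 lists had an adjusted p = 0.685 with an estimated correlation. CYC1, which encodes cytochrome c, was at 230 ± 1.92 FPKM in NR and 135 ± 45.2 in CR and did not pass (adjusted p = 0.087), although it passed as lower under median scaling, after quantile normalization and without CR A (log2 fold -1.15). Neither did HAP4, an activator of respiratory genes (log2 fold 0.42, adjusted p = 0.27), or ATP1 (0.92, adjusted p = 0.056). HAP4 passed as higher without CR B (0.72), and ATP1 without CR B (1.18), without CR A (0.66), after quantile normalization and among rows at their R64 position only. The row named COX4 lay outside the R64 gene, with a log2 fold of 0.13 that turned negative under both scalings. Of 8 genes encoded in mitochondrial DNA 4 could be tested, and 1 fell, COX1 (log2 fold -1.69, adjusted p = 0.021), whose row overlaps those of its intron reading frames. That list had 1 lower gene when adjusted over the list alone, a median log2 fold of 0.84, from -0.31 in CR A and 1.72 in CR B, and no call (camera adjusted p = 0.99).

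The low-affinity glucose transporter genes HXT3 and HXT1 and most of the changed glycolytic genes fell. HXT3 and HXT1 went from 915 ± 14.6 to 11.8 ± 0.427 FPKM (IV, 1162957 to 1164660, log2 fold -6.16, SE 0.19, adjusted p = 0.00075) and from 170 ± 104 to 6.48 ± 1.07 FPKM (VIII, 290913 to 292625, log2 fold -4.37, SE 0.46, adjusted p = 0.0057). HXT4 fell from 345 ± 32.1 to 38.6 ± 35.0 FPKM and RGT2, a sensor of high glucose, by 0.98 on the log2 scale. HXT2 (log2 fold 1.11, adjusted p = 0.073) and HXT5 (0.58, adjusted p = 0.12) did not pass, but HXT2 passed as higher without CR B (1.52) and HXT5 without CR A (0.81). HXT6 and HXT7 are near-identical, with 4.46% unique stretches, and were listed at 0.886 and 5.52 FPKM in NR and 4.90 and 13.2 in CR, values that cannot be assigned to either gene and that passed as higher without CR B. The list of 15 tested transporters and sensors, of 19 with a row, had 1 higher and 4 lower, the same numbers when adjusted over the list alone, and no call (median -0.20, camera adjusted p = 0.32). The higher gene was SNF3, a sensor of low glucose (log2 fold 0.86), chosen after its values were seen. In glycolysis 8 of 17 genes fell and 2 rose, 12 and 2 when adjusted over the list alone (median -1.53, camera adjusted p = 0.00098, adjusted p = 0.685 with an estimated correlation). FBA1, the aldolase gene, fell from 33263 ± 6107 to 5090 ± 1702 FPKM, CDC19, the pyruvate kinase gene, from 9859 ± 1042 to 1564 ± 578, and TDH1 from 2985 ± 669 to 468 ± 106. TDH2 fell too, by 3.63 on the log2 scale, with 50.8% of its stretches unique. The 2 genes that rose encode sugar kinases, HXK1 (4.21-fold, adjusted p = 0.033) and GLK1 (log2 fold 1.31), the latter chosen after its values were seen. HXK2 (log2 fold -1.09, adjusted p = 0.21), PGK1 (-1.72, adjusted p = 0.065) and TDH3 (-0.94, adjusted p = 0.12) did not pass. PGK1 passed as lower under both scalings, without CR A (-2.47) and without CR B (-0.98), and HXK2 (-1.97) and TDH3 (-1.36) passed as lower without CR A. HXK2 was at 756 and 1083 FPKM in NR A and NR B and at 780 and 230 in CR A and CR B. The median of the list was -0.98 in CR A and -1.97 in CR B against the NR mean. Ethanol fermentation had 2 lower of 7 genes, also 2 when adjusted over the list alone (median -0.57, camera adjusted p = 0.024, adjusted p = 0.685 with an estimated correlation). They were PDC1, a pyruvate decarboxylase gene (2109 ± 342 to 850 ± 242 FPKM), and ADH4 (700 ± 190 to 46.7 ± 5.61 FPKM), whereas ADH1 was at 3651 ± 581 and 3740 ± 2129 FPKM and passed, as lower, only without CR A (log2 fold -0.70). That list lost its call without NR B (adjusted p = 0.096) and without CR B (adjusted p = 0.11), and its median was -0.28 in CR A and -0.92 in CR B. SUC2, the invertase gene, rose 5.77-fold, from 126 ± 16.7 to 729 ± 221 FPKM. With it rose the maltose genes MAL31 (3.70-fold), MAL11 (2.93-fold) and MAL33 (2.69-fold), 4 of 10 tested genes of 12 for galactose, maltose and sucrose use, 5 when adjusted over the list alone (median 0.82, camera adjusted p = 0.021, adjusted p = 0.685 with an estimated correlation).

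Most ribosome biogenesis genes fell. Of 75 ribosome biogenesis genes 56 fell and none rose, 66 when adjusted over the list alone, with a median log2 fold of -1.88 (camera adjusted p = 2.8e-20, adjusted p = 0.685 with an estimated correlation). EBP2 fell from 2044 ± 236 to 182 ± 25.5 FPKM (XI, 125759 to 127042, log2 fold -3.49, SE 0.24, adjusted p = 0.0027). NOP58, a core protein of box C/D ribonucleoproteins, fell from 1154 ± 76.8 to 154 ± 21.6 FPKM. Cytosolic ribosomal protein genes had 26 lower and none higher of 137, 17 when adjusted over the list alone, and 134 had a negative fold (median -0.93, camera adjusted p = 1.1e-12, adjusted p = 0.685 with an estimated correlation). Of the 137 rows 12 lay away from the R64 gene, 8 of them among those that fell, including the 4 with the smallest adjusted p (RPS25B, RPS29A, RPS26B and RPL24A). Among the other 125 rows 18 fell, with a median of -0.92. In translation initiation and elongation 11 of 33 genes fell, or 13 with 1 higher when adjusted over the list alone (median -1.06, camera adjusted p = 5.8e-06, adjusted p = 0.685 with an estimated correlation). FUN12, the gene for eukaryotic initiation factor 5B, fell from 2038 ± 28.2 to 359 ± 31.96 FPKM. TIF1 fell from 12.8 ± 2.36 to 2.28 ± 1.45 FPKM, with 10.2% unique stretches. The gene higher only within the list was TIF4632, chosen after its values were seen. Against the NR mean, the medians in CR A and CR B were -1.51 and -2.28 for ribosome biogenesis, -0.46 and -1.39 for cytosolic ribosomal proteins and -0.59 and -1.34 for translation.

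**Figure D3:**
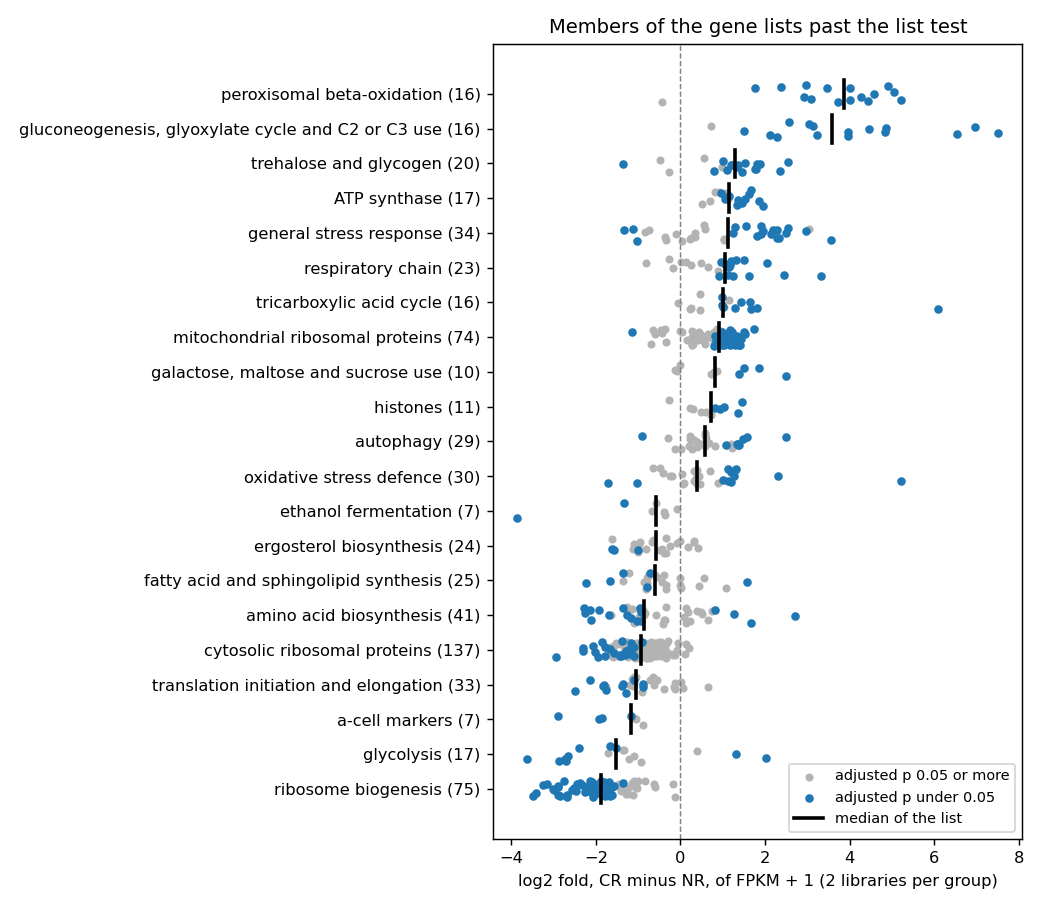
Log2 fold (CR minus NR, of FPKM + 1) of each member of the 21 gene lists past the set test, with the number of members tested in brackets. Blue points have an adjusted p under 0.05, grey points do not, and black bars are medians, which ran from -1.88 for ribosome biogenesis to 3.86 for peroxisomal beta-oxidation.

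Of the biosynthetic genes that changed, most fell. In amino acid biosynthesis 13 of 41 tested genes fell and 4 rose, or 18 and 5 when adjusted over the list alone (median -0.86, camera adjusted p = 0.0088, adjusted p = 0.711 with an estimated correlation). The histidine genes HIS4 (270 ± 11.6 to 61.8 ± 18.1 FPKM) and HIS5 and the aromatic pathway gene ARO4 (722 ± 74.9 to 152 ± 58.1 FPKM) fell. BAT2, a branched-chain aminotransferase gene, rose 6.70-fold. ARG3 and TRP1 rose as well, chosen after their values were seen. Ergosterol synthesis had 3 lower of 24 genes, ERG5, ERG25 and ERG27, but 0 in limma when adjusted over the list alone, with 7 at an unadjusted p under 0.05 (median -0.57, camera adjusted p = 0.011, adjusted p = 0.711 with an estimated correlation). For fatty acid and sphingolipid synthesis 5 of 25 genes fell and 1 rose, 4 and 1 when adjusted over the list alone (median -0.61, camera adjusted p = 0.011, adjusted p = 0.703 with an estimated correlation). IFA38, a gene of very long chain fatty acid elongation, fell from 435 ± 52.7 to 93.1 ± 25.9 FPKM, the ceramide synthase gene LAC1 from 208 ± 1.48 to 65.0 ± 9.89 and SUR2 from 289 ± 13.1 to 115 ± 34.4. TSC13 and PHS1 fell as well, chosen after their values were seen, while SUR1 rose 3.02-fold. Without CR B the ergosterol list (adjusted p = 0.10) and the fatty acid list (adjusted p = 0.062) lost their calls. Their medians in CR A and CR B were -0.25 and -0.88 for ergosterol, -0.21 and -0.73 for fatty acids and sphingolipids, and -0.36 and -1.13 for amino acids.

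Most storage carbohydrate genes rose, and a part of the stress genes did. Of 20 trehalose and glycogen genes 15 rose and 1 fell, 16 and 1 when adjusted over the list alone (median 1.28, camera adjusted p = 9.2e-05, adjusted p = 0.685 with an estimated correlation). The acid trehalase gene ATH1 rose from 22.9 ± 0.295 to 137 ± 0.949 FPKM, and the glycogen debranching gene GDB1 and the glycogenin gene GLG1 rose 5.16-fold and 3.72-fold. PGM1 fell (log2 fold -1.36), chosen after its values were seen. In the general stress list 16 of 34 genes rose and 3 fell, 17 and 3 when adjusted over the list alone (median 1.14, camera adjusted p = 0.00087, adjusted p = 0.685 with an estimated correlation). HSP12, a small heat shock protein gene, rose from 3525 ± 1853 to 38715 ± 2107 FPKM and RTN2 from 154 ± 7.65 to 876 ± 106. HSP26, another small heat shock protein gene, went the other way, from 247 ± 16.4 to 114 ± 8.01 FPKM (adjusted p = 0.017), as did MSN4, which encodes a stress transcription factor (51.6 ± 1.27 to 24.8 ± 3.53 FPKM, adjusted p = 0.021). The other gene that fell was DDR48, chosen after its values were seen. MSN2 did not pass (log2 fold 0.11, negative under median scaling). Oxidative stress defence had 10 higher and 2 lower of 30 genes, 11 and 2 when adjusted over the list alone (median 0.39, camera adjusted p = 0.022, adjusted p = 0.685 with an estimated correlation), and lost its call without NR A (adjusted p = 0.054) and without CR A (adjusted p = 0.075). CTT1, the cytosolic catalase gene, rose 2.47-fold and the glutathione peroxidase gene GPX1 5.17-fold. SOD1 (log2 fold 0.43) and SOD2 (0.04, negative under both scalings) did not pass, but SOD1 passed as higher without CR B (0.79). AHP1 and GRX3 fell, chosen after their values were seen. Of 29 autophagy genes 8 rose and 1 fell, 9 and 1 when adjusted over the list alone (median 0.58, camera adjusted p = 0.0011, adjusted p = 0.685 with an estimated correlation). The receptor gene ATG34 rose 6.01-fold, ATG33, which acts in the turnover of mitochondria, 3.04-fold, and ATG9 2.73-fold, and the lower gene was ATG27, chosen after its values were seen.

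Genes of NAD metabolism and the sirtuins, a focus of work on calorie restriction, moved both ways. Of 25 genes 6 rose and 6 fell, 6 and 8 when adjusted over the list alone, with no call for the list (median -0.18, camera adjusted p = 0.47). PNC1, the nicotinamidase gene, rose from 1673 ± 108 to 3670 ± 513 FPKM (2.19-fold, adjusted p = 0.036), a call that was lost without the filter on low values and with the rows without a gene ID included. NMA1 and NMA2, genes of NAD synthesis, rose 3.12-fold and 2.29-fold, and the sirtuin gene HST2 rose 2.29-fold. SIR2 was at 17.9 ± 3.91 FPKM in NR and 19.8 ± 0.751 in CR, a log2 fold of 0.15 (SE 0.24, adjusted p = 0.65). The reference genes ACT1 (2054 ± 17.1 and 1914 ± 371 FPKM), ALG9 (30.0 ± 7.85 and 37.2 ± 0.109) and TAF10 (195 ± 29.0 and 172 ± 10.5) did not pass.

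Nutrient uptake lists held opposite changes. For sulfur and methionine 9 of 22 tested genes rose and 5 fell, 11 and 7 when adjusted over the list alone (median 0.51, camera adjusted p = 0.13). MET28, a regulator of sulfur genes, rose 9.61-fold, the permease gene MMP1 12.8-fold and MET2 4.94-fold. CYS4, MET6, MET22, SAM1 and SAM2 fell, chosen after their values were seen. In iron uptake 7 of 21 genes rose and 1 fell, the same numbers when adjusted over the list alone (median 0.29, camera adjusted p = 0.25). The siderophore transporter gene SIT1 and the haem oxygenase gene HMX1 rose 4.50-fold and 4.05-fold, while FET4, a low-affinity iron transporter gene, fell from 141 ± 9.41 to 16.7 ± 1.59 FPKM. Of 14 tested phosphate genes 3 rose and 3 fell, 3 and 4 when adjusted over the list alone (median -0.02, positive after quantile normalization, camera adjusted p = 0.82). PHO3, an acid phosphatase gene, fell from 214 ± 71.7 to 11.3 ± 2.48 FPKM, while the phosphate transporter gene PHO89 rose 5.74-fold and SPL2 8.20-fold. PHM6 fell by 1.83 on the log2 scale. PHO5 fell and PHO8 rose, chosen after their values were seen. ZPS1 and ZRT1 were among the 10 largest falls. ZRT1, a high-affinity zinc transporter gene, went from 794 ± 549 to 18.3 ± 8.24 FPKM (VII, 20978 to 22108, log2 fold -5.23, SE 0.58, adjusted p = 0.0061) and ZPS1 from 1666 ± 186 to 36.9 ± 0.993 (XV, 34658 to 35407, log2 fold -5.46, SE 0.21, adjusted p = 0.00075). The others were YLR466C-B (-4.77), ADE17 of purine synthesis (-4.39), CGR1 of ribosome biogenesis (-3.90), YOR293C-A (-3.75) and HXT3, HXT1, PHO3 and ADH4, given with their groups. YLR466C-B is absent from RefSeq, has 24.4% unique stretches and was listed at 0 in both CR libraries.

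Among mating genes, 4 of 7 a-cell markers fell. All 7 a-cell markers had a negative fold, and 6 fell when adjusted over the list alone (median -1.17, camera adjusted p = 0.0013, adjusted p = 0.685 with an estimated correlation). The a-factor genes MFA2 and MFA1 fell from 54424 ± 2134 to 7708 ± 3657 FPKM and from 6814 ± 374 to 1885 ± 272, and ASG7 and the protease gene BAR1 fell 2.26-fold and 3.90-fold. The median of the list was -1.02 in CR A and -1.67 in CR B. None of the 4 alpha-cell markers passed limma at an adjusted p, in all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, STE3, chosen after its values were seen (median 0.08, negative under median scaling, camera adjusted p = 0.85), and SAG1 was at 14.2 ± 1.60 and 16.5 ± 1.25 FPKM. Among 10 haploid-specific genes GPA1, SST2, FAR1 and HO fell, a count of 4 lower and 2 higher when adjusted over the list alone, with no call (median -0.32, camera adjusted p = 0.22). The 2 higher were RME1 and NEJ1, chosen after their values were seen. In the cell cycle list 6 of 25 genes fell and 1 rose, 8 and 2 when adjusted over the list alone, and it missed the threshold (median -0.44, camera adjusted p = 0.054, adjusted p = 0.723 with an estimated correlation). It passed without NR B (adjusted p = 0.030) and without CR A (adjusted p = 0.0095), and among rows with 50% or more unique stretches (adjusted p = 0.0497). The S-phase cyclin gene CLB6 fell from 9.12 ± 1.12 to 1.23 ± 0.199 FPKM, and SIC1, an inhibitor of cyclin-dependent kinase, rose 2.85-fold. Of 11 histone genes HHT1, HHF2, HTA1 and HHT2 rose with HTA2, the last chosen after its values were seen. That made 5, also 5 when adjusted over the list alone (median 0.72, camera adjusted p = 0.016, adjusted p = 0.703 with an estimated correlation). Proteasome genes had 5 higher and 2 lower of 33, 1 and 0 when adjusted over the list alone, with no call (median 0.28, camera adjusted p = 0.23). RPN4, the transcription factor of proteasome genes, rose 3.87-fold, PRE4 and PUP3 rose 2.60-fold and 2.23-fold, PRE2 fell 2.25-fold, and PRE8, PRE10 and RPT2 passed too, chosen after their values were seen. Among 20 meiosis and sporulation genes DMC1, a meiotic recombinase gene, rose 17.9-fold and MEI4 fell (log2 fold -0.93, adjusted p = 0.049). Over the list alone 1 was higher and 0 lower, and the list had no call (median 0.29, camera adjusted p = 0.52). Of 91 Ty element rows 3 reached the filter and 0 passed limma, also 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05 (median 0.02, mean 0.07, with a downward camera direction and adjusted p = 0.99). The Ty median turned negative under median scaling.

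In all, 21 of 33 lists passed camera at its preset correlation, 12 upward and 9 downward. With an estimated correlation 0 lists passed in limma, with adjusted p-values from 0.685 to 0.994 and 1 list, that of gluconeogenesis, at an unadjusted p = 0.035. Fry, which asks whether a list's own genes move on balance in a given direction, passed 7. Of these 4 were among the 21: gluconeogenesis, peroxisomal oxidation, trehalose and glycogen, and autophagy. The 3 others were hexose transporters and sensors, sulfur and methionine, and meiosis and sporulation. Ribosome biogenesis (fry adjusted p = 0.097), glycolysis (0.15), the respiratory chain (0.057) and cytosolic ribosomal proteins (0.17) did not pass fry. The medians in CR A and CR B also lay on opposite sides of 0 for phosphate (0.11 and -0.14), alpha-cell markers (0.25 and -0.09) and Ty elements (0.08 and -0.04), none of which had a call. Some named genes overlap another row, and reads of the overlap cannot be assigned, since the use of strand in counting is not given in the sources used here and would not part rows on the same strand. They were ARO9, ATG34, ATP1, CDC19, ERG27, MAL11, MET2, MET28, PGK1, POL30, RRP14, RRP15, SIR2 and YML089C on the opposite strand and COX1, FDH2, HXK1, NMA2 and NOP58 on the same strand.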

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

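All tests in this part were chosen only after the result was seen.

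Some noncoding RNAs, which the gene comparison did not use, had a higher level in CR B than in both NR libraries, and RPR1 and SCR1 had one in CR A too. The median of 40 snoRNAs under 150 nt was 6421 and 5918 FPKM in NR A and NR B, 4433 in CR A and 48933 in CR B. The median of 32 measured transfer RNA rows was 242 and 249 FPKM in NR, 246 in CR A and 1564 in CR B, with 20, 22, 18 and 31 of the rows above 0. Most of these rows were mitochondrial, as were most of those above 0 in CR B but not in CR A. In CR A tA(UGC)Q (770 FPKM) lay at 5 times tI(GAU)Q (154 FPKM), a row of equal length, as whole fragments would give. However, tQ(UUG)Q, also 76 nt long, was at 486 FPKM, which is no whole multiple. With the annotated length, the value of 1 fragment estimated from long genes would instead put many fragments behind these values. Whether that value holds for rows this short was not tested. The number of fragments behind low transfer RNA values is thus not known and may be as low as 1. Ribosomal RNA rows with a signal, 2 of 8, were the mitochondrial 15S_RRNA and 21S_RRNA. Their median was 40.6 and 35.8 FPKM in NR, 32.6 in CR A and 83.3 in CR B. NME1, the RNA of RNase MRP, was at 387 and 428 FPKM in NR, 299 in CR A and 5327 in CR B. RPR1, the RNA of RNase P, was at 817 and 748 FPKM in NR, 2267 in CR A and 3485 in CR B. SCR1, the signal recognition particle RNA, was at 2351 and 1988 FPKM in NR, 3899 in CR A and 9732 in CR B.

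The increase in CR B went with length, as short snoRNAs had a median log2 CR B minus CR A of 3.78 (SD 1.10) and the 18 transfer RNAs above 0 in both 2.10 (SD 1.93), but the 36 snoRNAs of 150 nt or more had 0.50 (SD 0.67), and 7 of box C/D among these 0.80 (SD 0.91). Of the longer RNAs NME1, 340 nt long, was 17.8-fold higher in CR B, and SNR63, SNR80 and SNR70 differed by 2.16, 2.02 and 1.98 on the log2 scale. The mitochondrial 15S_RRNA (1649 nt) and 21S_RRNA (4439 nt) were 1.70-fold and 2.87-fold higher in CR B than in CR A. The tested mitochondrially encoded genes had a median log2 CR B minus CR A of 1.71. These go against a trend with length alone. Some of the 18 transfer RNAs are mitochondrial too, so length and origin are not separated in them. The 56 protein-coding rows under 150 nt had a median of 0.41 (SD 1.67). They were not matched in length to the short snoRNAs, of 78 to 136 nt, and varied widely. An effect of the length term of FPKM therefore stays open. A rise caused by calorie restriction is argued against by CR A, where the short snoRNAs had a median of -0.49 against the NR mean (SD 0.73), 30 of 40 of them lower. A larger share of short RNA entering the CR B library, as a kit for small RNA may take up, is a candidate explanation that stays open, and no library batch is given in the sources used here.

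Of 187 protein-coding genes with under 10% of their 32-nt stretches unique, 107 were listed at 0 FPKM in every library, and their median was 0 in each. The 6 translation factor genes with under 50% unique stretches had a median of 6.41 FPKM against 326 for the 27 with 90% or more. Of cytosolic ribosomal protein genes the 10 with under 50% had a median of 35.8 FPKM against 986 for the 88 with 90% or more, but RPL41A and RPL41B, with 19.1% unique stretches, were at 17038 and 39894 FPKM. How reads with several matches were treated is not given in the sources used here, and the reason for these levels was not tested.

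The CR libraries differed more from each other than the NR libraries did, with an SD of log2 B minus A of 0.64 in CR and 0.38 in NR. Fewer counted fragments are argued against by the fifth of genes with the highest level, where the ratio of the CR to the NR SD was 2.12 (0.63 and 0.30), and a trend with transcript length by an SD of 0.62 that remained in CR after the medians of 20 length bins were subtracted. Whether the CR B culture had gone further along the same change could not be decided. Relative to all genes, 9 of 9 lists lower in CR had a lower median in CR B than in CR A, against 8 of 12 lists with no call (Fisher's exact test, two-sided, p = 0.104), and 4 of 12 lists higher in CR had a higher median, against 4 of 12 with no call (p = 1). Against 8 of 12, even 9 of 9 could not bring Fisher's test under 0.05. For the lists lower in CR the test thus could not have favoured the explanation. All lists also rest on the same 2 CR libraries and are not independent. A biological difference between the CR cultures stays open, since harvest time and density are not given in the sources used here.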

How the results depend on the processing

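The 4 choices of rows were added after seeing the data, and all other settings were fixed before the data were examined. No setting turned the direction of a gene called in the reported fit. Pseudocounts, scaling, the intensity trend, the 2-fold threshold and the choices of rows kept the counts of higher and lower genes within 1.5 times of 1126 and 836. Without a filter on low values 464 genes were lower and 778 higher, and 20 named genes lost their call; that setting tests 6720 rows, 194 of them at 0 in every library. An estimated correlation left 0 of 21 lists. Fry, which asks another question than camera, passed 7, of which 4 were among the 21. Leaving out 1 library gave 75 to 1654 higher genes, 47 to 1668 lower genes and 18 to 21 lists; the lone library of a group was then assumed to vary like the other group. With the replicate block 1150 genes were higher, 986 lower and 22 lists passed, cell cycle being the added list (adjusted p = 0.049, range over its alternatives 0.0095 to 0.723, the highest with an estimated correlation), and HHT2, HTA1, MEI4, PDC1, PNC1 and PRE2 lost their call. Whether replicates of the same letter shared a batch is not given in the sources used here. The B minus A differences of NR and CR correlated at 0.083 over genes, which is low but does not exclude a shared batch. Why these calls were lost was not tested. The cause of the other shifts was not tested. Depth was estimated only, so no floor was set for genes listed at 0.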

Other observations

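The gene lists, the test with noncoding rows and the tests of hypotheses in this part were chosen only after the result was seen, as were the genes singled out in it. The lists were drawn up around genes seen to change, so that their counts and medians describe these genes and test nothing.

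Other genes of purine and one-carbon metabolism fell besides ADE17. ADE13 fell by 3.72, the serine hydroxymethyltransferase gene SHM2 by 3.70 and ADE1 by 3.45 on the log2 scale, while ADE16, which shares its function with ADE17, did not pass (0.32, adjusted p = 0.29). In a list of 16 such genes 11 were lower, with a median log2 fold of -2.51. The proline permease gene PUT4 rose 32.7-fold and PDH1 of the methylcitrate cycle 31.4-fold, and 11 of 12 genes listed for proline, methylcitrate and carnitine use were higher (median 3.78). SPG4 rose 30.8-fold and TMA10 21.6-fold, in a list of 13 genes of stationary phase and small stress proteins in which 9 rose and SNZ1 fell (median 2.29).

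Among noncoding RNAs, tested with all rows included, the telomerase RNA TLC1 fell (log2 fold -1.87, SE 0.27, adjusted p = 0.013), from 343 and 354 FPKM in NR to 76.2 and 117 in CR, and RPR1 rose (1.85, SE 0.34, adjusted p = 0.022). Of 32 transfer RNA rows 3 rose in limma, CDC65 (log2 fold 2.35, adjusted p = 0.045) and the mitochondrial tI(GAU)Q and tM(CAU)Q2. The mitochondrial rows were listed at 0 in both NR libraries and at 154 and 133 FPKM in CR A. The number of fragments behind those CR A values is not known and may be as low as 1, so their calls are uncertain. Of 9 RNAs annotated only as noncoding, RNA170 rose and RUF23 and PWR1 fell. Of 36 snoRNAs of 150 nt or more 6 fell, among them SNR17B (log2 fold -2.17, adjusted p = 0.0075), and of 40 shorter ones 0 passed limma, with 0 at an unadjusted p under 0.05. Rows of 600 gene IDs absent from RefSeq had a median log2 CR B minus CR A of 0.37, against -0.17 for rows in RefSeq.

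LEU2, MET17 and URA3 were listed at 0 FPKM in every library although their sequences are unique in the genome, as were YDL007C-A and YOL166W-A. A hypothesis is that the strain lacks LEU2, MET17 and URA3. Their nearest unique neighbours were expressed, the lowest at a mean of 37.4 FPKM, next to URA3. That would also hold if the genes were present but not expressed or not counted, so it does not decide the hypothesis. HIS3 had a mean of 69.3 FPKM, and the a-cell receptor gene STE2 230 against 6.37 for STE3 of alpha cells.

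ZPS1, ZRT1 and ADH4, known targets of the zinc regulator Zap1, were among the largest falls. A hypothesis is that NR cells met less zinc than CR cells. The other 7 genes of the zinc list had a median log2 fold of -0.46 (SD 0.75) with 2 lower, VEL1 and IZH2, so the hypothesis could not be decided. The list was short and did not include FET4, given with iron uptake, which fell.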
